A study of Danio rerio with 60 samples.

How the data were processed

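The series follows lineages in zebrafish by short insertions and deletions, called scars, that Cas9 leaves in GFP. Cas9 and a single guide RNA (sgRNA) against GFP were injected into embryos of 1 cell, and the target was then amplified from genomic DNA or RNA and sequenced. Of the 60 samples, 59 are pooled amplicon libraries and 1 is a whole-genome library of a fish that was homozygous for histone-GFP, per the labels. An amplicon library has 96 barcode columns, and each barcode listed for it in the labels stands for 1 embryo, 1 pool of embryos, 1 section of an embryo or 1 piece of a caudal fin.

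For each amplicon library the authors deposited raw counts, per the file headers the number of reads for each target sequence and each barcode, with an alignment code, the sequence of 76 bases and a start position in the alignment reference. Alignment used BWA, whose version is not given, and the genome build danRer10, per the submitters' processing notes. The filters that decided which sequences were listed are not stated. For the whole-genome library the deposited values are estimated counts, reads per bin of 1000 bases in which a read that spans a border is divided between the bins. This reading of the bins rests on the values themselves, since they are fractional per bin and whole numbers in total per chromosome. Deposited tables of fin pieces give the ray or interray number and the position along the fin for each barcode.

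Groups were taken from the titles and barcode lists of the labels. Where the name of a deposited file and its label disagreed, as for the 8 h and 48 h libraries of dynamics experiment 4, the label was kept, because the barcodes with reads were those that the label lists. Names also disagreed for library 1 of RF8 and libraries 2 and 3 of RM5, whose labels list all 96 barcodes, so the barcodes cannot decide. These labels were kept too, and 27 of the 28 embryos with a scar in the first, 8 of 9 in the second and 11 of 11 in the last carried a germline scar found in the other libraries of the founder. For PF1-3 and PF1-4 the file names give PF1 without the founder's number. One group is called dCas9-labelled here, because its title names dCas9 while its treatment text is incomplete. Stages, doses and forms of Cas9 were copied from the labels.

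A barcode was used when it had at least 1000 target reads. Of 2257 listed barcodes, 1141 were kept and 1116 were left out, most of them from F1 libraries in which the labels list all 96 barcodes. The uncut target was the most abundant sequence in embryos without sgRNA, and every other sequence was called a scar. The scarred share is the percentage of a barcode's reads that were not the uncut target. A scar was counted as present in an embryo at 0.5% of its reads and at least 10 reads. The effective number of scars is the exponential of the Shannon entropy of scar shares among scarred reads. Length classes and length changes divisible by 3 are shares of the scarred reads without clipped ends, since clipped ends leave the length unknown, and insertions and deletions that cancel count as divisible by 3 there but not in the share of all scarred reads. An F1 embryo carried a scar when at least 5% of its reads held it, and a germline scar was carried by at least 2 F1 embryos of a founder. Scars are named by their alignment codes, in which M counts aligned bases, D deleted bases, I inserted bases and S bases at an end that did not align. A suffix such as _2 tells sequences with the same code apart. Positions of deleted bases were given only where the deletion applied to the reference rebuilt from the reads returned the observed sequence exactly.

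The kept barcodes had between 1006 and 14772765 reads, with a median of 84230. Intervals are binomial exact (Clopper-Pearson) intervals at the 95% level. At 1006 reads a share of 50% has an interval from 46.9% to 53.1%, and at 84230 reads from 49.7% to 50.3%. A scar with 0 reads at a depth of 1000 reads could hold up to 0.3% of the target. These intervals and limits cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

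The replicate was the embryo, and for F1 clutches the founder, never the read. Differences in means were tested by two-sided permutation tests, exact where a group had fewer than 10 members and with 100000 resamples otherwise. Benjamini-Hochberg adjustment was applied over the 11 planned tests of embryos, over the 5 adjacent pairs of stages within each experiment, over the 10 named scars of each contrast and over 12 further measures in each of 4 contrasts. The test of RNA against DNA without sgRNA permuted molecules within each form of Cas9. Similarity of sections and fin pieces is Bray-Curtis similarity, 1 minus Bray-Curtis dissimilarity of the shares of all sequences, and 10000 permutations of section order or piece position gave its p. Neighbouring sections are consecutive barcode numbers. Neighbouring fin pieces lie 1 step apart along a ray or interray, or at adjacent numbers at the same level. The threshold was 0.05 throughout.

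The rule for named scars was fixed before the data were examined. It took the 10 scars with the highest mean share of scarred reads over the 24 h embryos injected with Cas9 mRNA, the 3 scars carried by most F1 embryos of each founder, and the 3 scars with the highest mean share in each fin collection and in each sectioned embryo. Scars named outside this rule (36M17D40M, 58M18S at 24 h, 56M1D20M, 17M7I52M, those in clipped reads with telomere repeats, and the combinations of scars in clutches PF1-3 and PF1-4) were chosen after their values were seen. The groups, tests and most alternative settings were also fixed before the data were examined. Alternatives covered the minimum number of reads, the handling of rare scars, thinning to 1000 reads, medians, leaving out embryos, libraries or founders, and each experiment alone.

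The permutation test of 24 h against 8 h in experiment 4 was tested on simulated data drawn from normal distributions with the spread of the groups. Of 400 simulations each, it called 4% with no difference planted, 31% with 10 percentage points, 79.5% with 20 and 97.5% with 30. For the named scars of protein against mRNA embryos, with both groups resampled from mRNA embryos, a 1.5-fold change was recovered in 61% of 200 planted scars, a 2-fold change in 92% of 200 and a 4-fold change in 100% of 200. In the same simulations 3.67%, 2.33% and 4% of 300 unchanged scars were called. Only decreases were planted. Real protein embryos spread more for some scars (29M6D47M, SD 15.6 against 5.00 with mRNA) and less for others (27M2D49M, 0.119 against 1.95). These rates need not hold for them. The test of neighbouring sections found planted clones of 6 sections in 100% of 100 simulations and called 5% of 100 simulations without clones.

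Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. Barcodes outside the labels, 53 of them in 8 libraries, entered no comparison. Chromosome 5 was not analysed here, and no genes were assigned to bins because the available gene coordinates belong to another genome build.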

Results

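The data hold 257869699 target reads from 59 amplicon libraries, with 466348 to 35906201 reads per library and a median of 2406306. The 1141 barcodes used were 186 injected or control embryos and embryo pools, 92 sections of embryos, 273 caudal fin pieces and 590 F1 embryos. Cas9 was injected as mRNA at 300 ng/µl or as protein at 1590 ng/µl, each with sgRNA at 25 ng/µl. A time course read DNA of embryos injected with Cas9 mRNA from 2 h to 6 d in dynamics experiments 3 and 4, with 106 single embryos from 8 h on and pools before that. Further groups were 12 embryos with Cas9 protein read from RNA, 12 dCas9-labelled embryos read from DNA, 45 embryos that received Cas9 without sgRNA, 2 sectioned embryos, 4 collections of fin pieces and F1 clutches of 6 founders. Median depth per barcode was 127125 reads at 8 h and 33067 at 24 h in experiment 4, 168542 in the protein group, 285839 in the dCas9-labelled group and 85422 in sections.

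The guide GGTGTTCTGCTGGTAGTGGT matched 1 site in the GFP target. The uncut read spans positions 1972 to 2047 of the transgene reference, and the 20 bases of the guide match positions 1995 to 2014 on the reverse strand. The PAM, the short motif that Cas9 needs beside its target, is CGG at positions 1992 to 1994, so the cut 3 bases from it lies between 1997 and 1998. The libraries list 15169 sequences, of which 3155 are single deletions. Of the reads with a single deletion, 88.1% were rebuilt exactly from the reference and 89.6% had a deletion that touches the cut.

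Deletions were the main kind of scar in the 106 single embryos injected with Cas9 mRNA. They made up 82.5% ± 5.79 of scarred reads (SD, n = 106), against 6.99% ± 3.4 for insertions, 2.95% ± 1.69 for both together and 7.53% ± 4.66 for other changes. Lengths are given for scarred reads without clipped ends, 92.5% ± 4.66 of scarred reads. Of these, length changes of 6 to 10 bases took the largest share of the 4 length classes, 38.4% ± 6.33. Changes of 11 to 20 bases took 29.2% ± 6.49, those of 1 to 5 bases 26.6% ± 5.79 and longer ones 5.75% ± 3.46. A length change divisible by 3, which keeps the reading frame, was found in 55.0% ± 6.39 of scarred reads without clipped ends and in 50.7% ± 6.35 of all scarred reads.

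The same 10 scars recurred in most embryos at 24 h, and together they held 53.5% ± 5.88 of scarred reads (SD, n = 18, range 43.8% to 65.8%). The most frequent, 29M6D47M, deletes the 6 bases from 1995 to 2000 and held 16.8% ± 5.00 of scarred reads. Next came 26M3D50M (deleting 1995 to 1997) with 7.04% ± 2.28, 27M11D49M (1988 to 1998) with 6.34% ± 1.77 and 31M18D45M (1985 to 2002) with 6.03% ± 2.16. The smaller 27M2D49M (1997 to 1998) held 4.11% ± 1.95. The longer 33M21D43M (1984 to 2004) held 3.06% ± 1.47, 27M9D49M (1990 to 1998) 2.97% ± 1.44, 27M6D49M (1993 to 1998) 2.61% ± 2.17 and 30M10D46M (1992 to 2001) 2.32% ± 1.01. The only insertion among them, 25M1I50M, adds 1 base after position 1997 and held 2.22% ± 0.729. In the 11 embryos with Cas9 mRNA alone, the mean share of these scars among all reads was at most 0.00507%, reached by 27M9D49M.

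**Figure D1:**
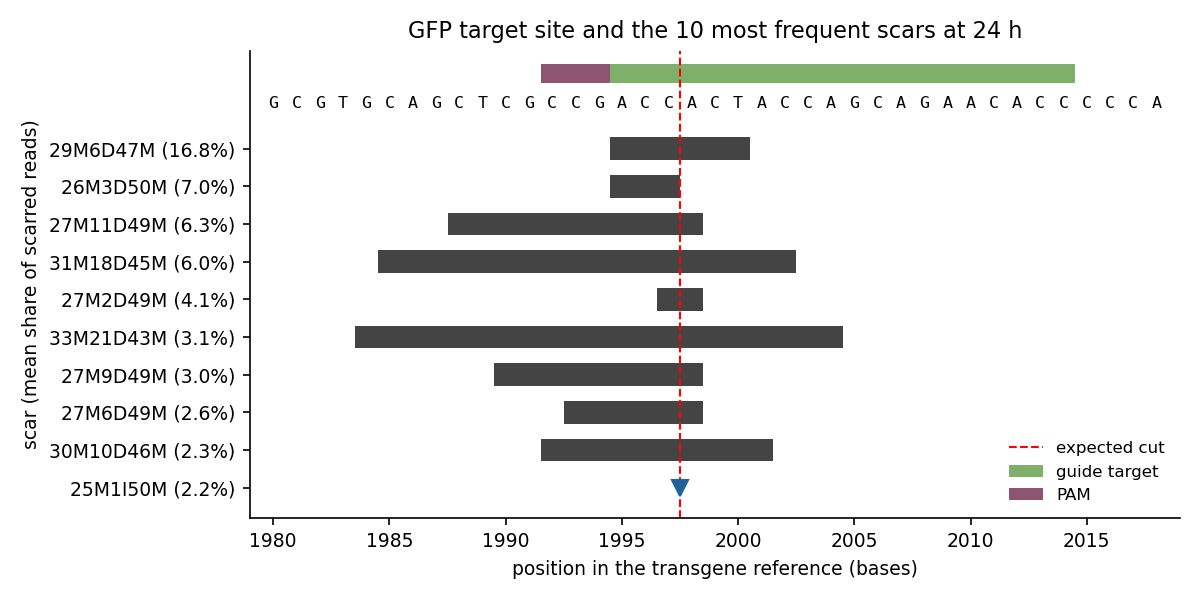
Map of the GFP target with position in the transgene reference (bases) on the horizontal axis and the 10 named scars, with their mean share of scarred reads at 24 h, on the vertical axis. Bars are deleted bases and the triangle is an inserted base; every one of the 10 touches or borders the expected cut between 1997 and 1998, and 29M6D47M is the most frequent at 16.8%.

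How often the same scar arises in separate embryos decides which scars can mark a lineage. The 18 embryos at 24 h held 99 scars at 0.5% of reads or more. The 10 named scars were each found in at least 11 of the 18 embryos, and 29M6D47M, 26M3D50M and 31M18D45M were found in all 18. After these 10, the most widespread scars were 36M17D40M and 58M18S, in 5 embryos each. In contrast 72 of the 99 scars (72.7%) were found in 1 embryo only. On average a scar was found in 2.79 embryos. Within experiments the share found in 1 embryo was 63.2% of 38 scars in the 8 embryos of experiment 3 and 73.5% of 83 scars in the 10 embryos of experiment 4.

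The time course asks when Cas9 mRNA makes its scars. Scars were present in the first pools: in experiment 4 at 2 h, 14.0% of reads (interval 13.97% to 14.04%) and 15.9% (15.7% to 16.1%) were scarred, and in experiment 3 at 2 h 11.1% (10.3% to 11.8%). At 4 h the pools of experiment 4 had 20.3% (20.23% to 20.27%) and 21.6% (21.58% to 21.62%), and that of experiment 3 had 28.3% (25.6% to 31.2%, 1034 reads). At 6 h they had 25.3% (25.3% to 25.4%) and 36.0% (35.9% to 36.1%) in experiment 4 and 28% (27.7% to 28.3%) in experiment 3. Pools are single values per barcode and were not tested.

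In experiment 4 the scarred share of single embryos rose from 29.2% ± 13.1 at 8 h to 57.9% ± 17.8 at 24 h (SD, n = 10 each). Distinct scars per embryo rose with it, from 11.7 ± 4.32 to 18.9 ± 5.26. On each measure 9 of 10 embryos at 24 h lay above the mean at 8 h. Later groups stood at 45.2% ± 22.6 at 32 h, 56.2% ± 17.9 at 48 h, 39.2% ± 22.7 at 72 h (n = 10 each) and 51.9% ± 25.2 at 6 d (n = 9). The step from 8 h to 24 h was 28.7 percentage points (permutation p = 0.00156, adjusted p = 0.00572 over 11 tests and 0.0078 over the 5 adjacent stages), and it was the only adjacent step of the 5 past the threshold. Distinct scars passed it as well (difference 7.2, permutation p = 0.00593, adjusted p = 0.0356 over 12 measures). A scar counts as distinct by its share of all reads, so a higher scarred share alone can raise this number. The effective number, taken among scarred reads, was 42.9 at 24 h and 51.6 at 8 h. From 24 h to 6 d the scarred share fell by 5.98 points, within the spread of embryos (exact permutation p = 0.551, adjusted p = 0.673). Each stage of experiment 4 was 1 library, so stage and library cannot be told apart.

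The step from 8 h to 24 h did not pass the threshold in experiment 3 (3.21 points, exact permutation p = 0.911), which had only 2 embryos at 8 h. Its embryos had 23.3% ± 0.156 scarred reads at 8 h (SD, n = 2), 26.5% ± 21.7 at 24 h and 43.3% ± 15.8 at 32 h (n = 8 each). They had 46.3% ± 18 at 48 h and 49.1% ± 23.4 at 72 h (n = 10 each), and 35.1% ± 13.8 at 6 d (n = 9). None of its 5 adjacent steps passed the threshold by permutation tests, with 0 at an unadjusted p under 0.05, and 6 d minus 24 h was 8.58 points (exact permutation p = 0.341, adjusted p = 0.469). At 24 h, experiment 4 lay 31.4 points above experiment 3 (exact permutation p = 0.00592, adjusted p = 0.0358 over 12 measures). The change between these stages, taken as 8 h minus 24 h, differed by -25.4 points between experiment 4 and experiment 3, short of the threshold (permutation p = 0.102, adjusted p = 0.128 over 5 stages). Of the 8 embryos of experiment 3 at 24 h, 6 came from 1 library with 18.9% ± 13.8 and the other 2 from a library of mixed stages with 49.5% ± 30.6.

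**Figure D2:**
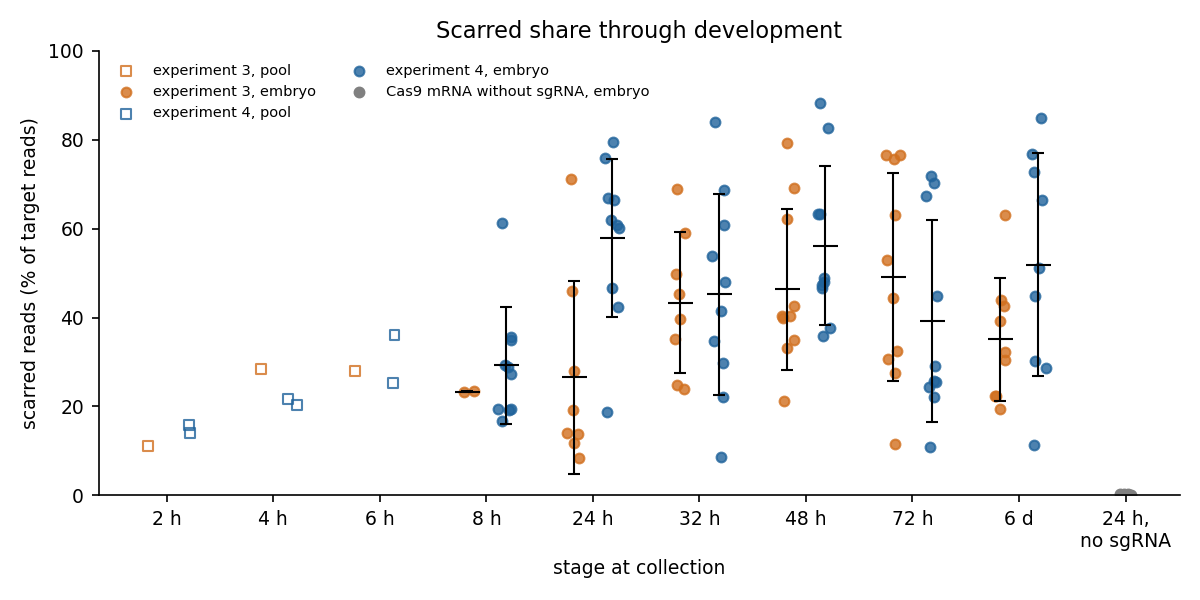
Scarred reads (% of target reads) against stage at collection in experiments 3 and 4, with single embryos as dots, pools as open squares, and mean with SD as bars. Experiment 4 rises from 29.2% at 8 h to 57.9% at 24 h, while embryos with Cas9 mRNA and no sgRNA lie at 0.162%.

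None of the planned tests of the mix of scars between early and later stages passed the threshold with the main settings. In experiment 4, 29M6D47M held 15.6% ± 4.56 of scarred reads at 8 h (SD, n = 10) and 14.2% ± 3.34 at 6 d (n = 9), and 26M3D50M held 8.58% ± 3.79 and 9.14% ± 2.25. Of the 10 named scars, 0 differed between 6 d and 8 h by exact permutation tests, and 0 had an unadjusted p under 0.05. Deletions made up 82.9% ± 6.59 of scarred reads at 24 h and 82.1% ± 4.86 at 8 h (n = 10 each, permutation p = 0.753, adjusted p = 0.83). The effective number of scars was 42.9 ± 9.38 at 24 h and 51.6 ± 13.4 at 8 h, a difference of -8.71 (permutation p = 0.108, adjusted p = 0.197). With scars under 1% of reads counted as uncut, the difference was 3.77 (permutation p = 0.00229). That limit is a share of all reads, so it weighs more on embryos with fewer scarred reads. Length changes divisible by 3 made up 53.0% ± 6.92 of scarred reads without clipped ends at 6 d (n = 18) and 55.8% ± 5.52 at 8 h (n = 12) over both experiments, a difference of -2.77 (permutation p = 0.256, adjusted p = 0.402). Without the farthest embryo of each group it was -4.74 (permutation p = 0.0344), and as a share of all scarred reads, an alternative chosen after seeing the data, -4.02 (permutation p = 0.0792). The test did not separate the experiments. Experiment 4 had 55.5% ± 6.67 at 6 d (n = 9) and 55.0% ± 5.38 at 8 h (n = 10). Experiment 3 had 50.5% ± 6.58 (n = 9) and 59.9% ± 5.87 (n = 2).

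Scars depended on the sgRNA. At 24 h the embryos with Cas9 mRNA and sgRNA had 44% ± 24.9 scarred reads (SD, n = 18), against 0.162% ± 0.0405 with Cas9 mRNA alone (n = 11). The lowest of the 18 had 8.38%, while the highest of all embryos without sgRNA had 0.376%. Embryos with Cas9 protein and sgRNA, read from RNA, had 98.3% ± 4.39 (n = 12, range 84.5% to 99.9%), against 0.240% ± 0.0529 with Cas9 protein alone (n = 12). Both differences passed the test (43.8 points, permutation p = 8e-05, adjusted p = 0.00044; 98.1 points, permutation p = 1e-05, the smallest that the resamples can give). Within experiments the mRNA difference was 26.4 points in experiment 3 (exact permutation p = 1.32e-05) and 57.7 points in experiment 4 (permutation p = 2e-05). No single change reached 0.5% of reads in any of the 45 embryos without sgRNA, where the highest single one held 0.207% and the most frequent leading change was 56M1D20M, in 21 embryos.

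The background without sgRNA was higher in RNA than in DNA. Its mean was 0.238% ± 0.0557 of reads in RNA (SD, n = 23) and 0.188% ± 0.0609 in DNA (n = 22). The difference of 0.0497 points passed the test (permutation p = 0.00592, adjusted p = 0.0163). It no longer did with barcodes from 100 reads (permutation p = 0.0692) or with reads thinned to 1000 (permutation p = 0.340). RNA and DNA had 0.237% and 0.162% with Cas9 mRNA, and 0.240% and 0.215% with Cas9 protein. Each combination of molecule and form of Cas9 was 1 library, so molecule and library cannot be told apart.

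Protein and mRNA embryos differed in how scarred reads were divided among scars. Embryos with Cas9 protein held 15.3 ± 3.82 distinct scars (SD, n = 12) and embryos with Cas9 mRNA 15.3 ± 7.43 (n = 18), a difference of 0 (permutation p = 1). The effective number of scars was 12.9 ± 5.59 with protein and 48.2 ± 10.8 with mRNA. Of the 10 named scars, 4 were lower with protein: 27M2D49M at 0.0537% ± 0.119 of scarred reads against 4.11% ± 1.95, 26M3D50M at 2.56% ± 5.95 against 7.04% ± 2.28, 27M6D49M at 0.629% ± 0.823 against 2.61% ± 2.17, and 30M10D46M at 0.870% ± 1.16 against 2.32% ± 1.01. Below the mRNA mean lay 12 of 12 protein embryos for 27M2D49M, 11 for 26M3D50M, 12 for 27M6D49M and 10 for 30M10D46M. The most frequent scar, 29M6D47M, had 17.3% ± 15.6 with protein and 16.8% ± 5.00 with mRNA (permutation p = 0.920).

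Adjusted p over the 10 scars was 1e-04 for 27M2D49M, 0.0123 for 26M3D50M, 0.0056 for 27M6D49M and 0.0055 for 30M10D46M by permutation tests. The effective number differed by -35.3 (permutation p = 1e-05, the smallest possible; adjusted p = 6e-05 over 12 measures), and the scarred share by 54.4 points (permutation p = 1e-05). For distinct scars the difference was 4.46 against experiment 3 alone (exact permutation p = 0.105) and -3.57 against experiment 4 alone (permutation p = 0.0870), and -16.7 with scars counted from 0.1% of reads (permutation p = 0.0176). Protein embryos were read from RNA and mRNA embryos from DNA. The 10 named scars were chosen by their high share in these mRNA embryos, which favours scars lower with protein. Where embryos with Cas9 mRNA were read from RNA, scarred reads made up 51.0% in 1 embryo barcode at 48 h and at most 82.9% in any of 92 sections at 24 h, below the lowest protein embryo (84.5%). Of the 4 scars lower with protein, RNA and DNA at 48 h held 1.72% and 1.35% of reads for 27M2D49M, 3.39% and 3.41% for 26M3D50M, 0.917% and 0.854% for 27M6D49M, and 0.551% and 0.95% for 30M10D46M. The effective number there was 51.0 in RNA and 67.0 in DNA. These are single barcodes and were not tested.

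**Figure D3:**
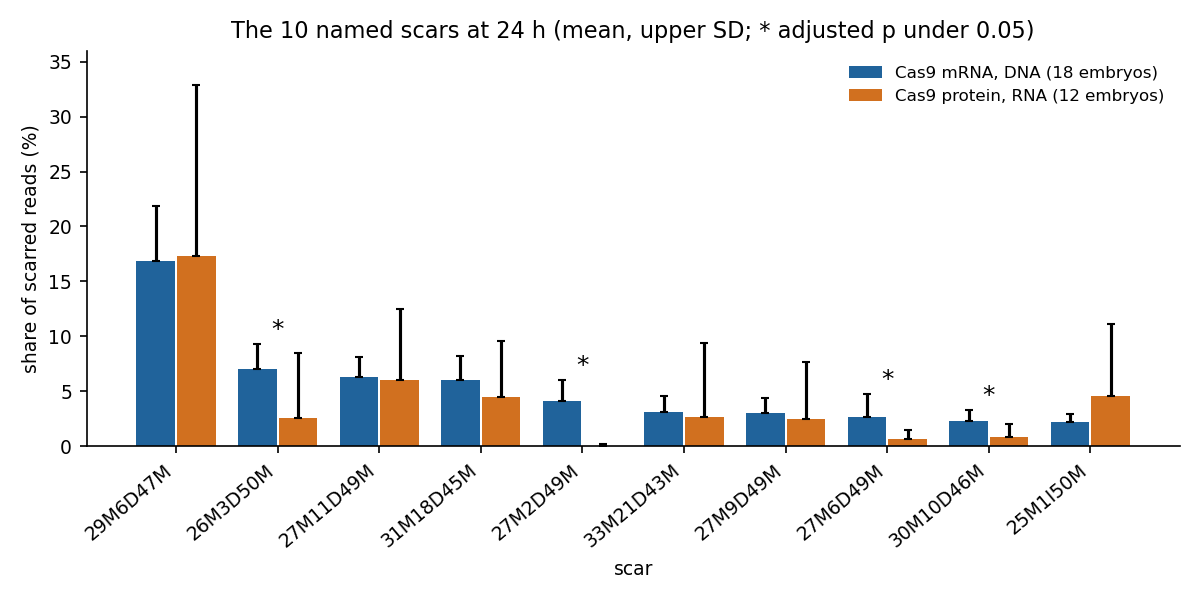
Share of scarred reads (%) held by the 10 named scars at 24 h in embryos with Cas9 mRNA (DNA, n = 18) and with Cas9 protein (RNA, n = 12), as bars of the mean with the upper SD. Stars mark the 4 scars with an adjusted p under 0.05, of which 27M2D49M has 4.11% with mRNA and 0.0537% with protein.

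Embryos of the dCas9-labelled group, injected with sgRNA, had scars at 24 h. Their scarred share was 25.5% ± 12.1 (SD, n = 12, range 10.5% to 48.5%), 25.3 points above Cas9 mRNA alone (permutation p = 1e-05, the smallest possible). Catalytically dead Cas9 binds DNA without cutting it. Their leading scar 29M6D47M held 17.0% ± 3.97 of scarred reads against 16.8% ± 5.00, and 27M2D49M 4.35% ± 0.872 against 4.11% ± 1.95. Of the 10 named scars, 0 differed after adjustment by permutation tests, while 27M9D49M and 25M1I50M had an unadjusted p under 0.05 (0.0455 and 0.0156). Compared with the 18 embryos with Cas9 mRNA, the difference in scarred share was -18.5 points, which did not pass after adjustment (permutation p = 0.0256, adjusted p = 0.0564). Against experiment 3 alone the difference was -1.04 (exact permutation p = 0.898) and against experiment 4 alone -32.4 (permutation p = 0.00025). Without library 1 of this group it was -18.3 (exact permutation p = 0.103) and without library 2 -18.6 (exact permutation p = 0.0956). With log10 reads as a covariate, an alternative chosen after seeing the data, it was -5.03 (permutation p = 0.544).

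RNA and DNA of the target were compared at 48 h in 1 barcode each, without replicates. Scarred reads made up 46.3% of DNA reads (interval 46.1% to 46.4%, 454060 reads) and 51.0% of RNA reads (50.8% to 51.2%, 230434 reads). The leading scar 29M6D47M held 7.75% of DNA reads and 9.86% of RNA reads, 27M11D49M 4.00% and 4.19%, and 26M3D50M 3.41% and 3.39%. The insertion 17M7I52M, named after its values were seen, held 1.11% of DNA reads and 2.45% of RNA reads. Across 1503 sequences, which are not independent replicates, Pearson's r between the shares was 0.998 and Spearman's rho 0.413. Without the uncut target r was 0.985. The molecules shared 563 of these sequences.

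In the 2 sectioned embryos, neighbouring sections were more similar in their sequences, uncut target included, than distant ones. In embryo TOMO-2, with 46 sections, similarity was 0.706 between consecutive sections and 0.545 between sections 21 to 47 numbers apart. In embryo TOMO-3, also with 46 sections, it was 0.809 and 0.714. The scar 29M6D47M led in both, with 10.6% ± 4.40 of reads per section in TOMO-2 and 7.56% ± 2.33 in TOMO-3 (SD over sections, n = 46 each). In TOMO-2, 27M9D49M followed with 5.61% ± 3.65, from 0.320% in section 41 to 12.2% in section 26, and then 31M18D45M with 3.43% ± 1.66. In TOMO-3, 31M18D45M held 4.33% ± 1.33 and 27M11D49M 4.24% ± 1.32. The uncut target held 35.8% ± 15.6 (17.1% to 88.0%) in TOMO-2 and 40.1% ± 6.15 in TOMO-3, and its changes count in these similarities.

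Similarity of consecutive sections exceeded that of all other pairs by 0.125 in TOMO-2 and 0.0707 in TOMO-3. In each embryo the permutation p was 1e-04, the smallest that the orderings drawn can give. Sections of an embryo are not replicates, so the test speaks of these embryos only, and section order was taken to be barcode number. Every pair of neighbouring sections therefore has consecutive barcodes. Reads leaking between consecutive barcodes cannot be told apart from position here.

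Fin pieces were also more similar to their neighbours, uncut target included, in the original fin and after regeneration. The deposited tables name zf1fin3 a repeat of the second regenerated caudal fin (Fin1-2), and Fin1-0 and Fin1-1 were taken from their numbers to be the original fin and the first regenerated fin. Pieces 1 step apart along a ray or interray had a similarity of 0.865 in Fin1-0, 0.865 in Fin1-1, 0.941 in Fin1-2 and 0.933 in zf1fin3. Pieces more than 5 numbers apart had 0.756, 0.734, 0.793 and 0.797. Scarred reads made up 26.5% ± 11.1 in Fin1-0 (SD over pieces, n = 65), 26.4% ± 13.8 in Fin1-1 (n = 79), 23.6% ± 9.29 in Fin1-2 (n = 43) and 23% ± 9.32 in zf1fin3 (n = 80).

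Of the scars named in fins, 29M6D47M held 2.46% ± 4.58 of reads per piece in Fin1-0, 2.88% ± 4.45 in Fin1-1, 2.43% ± 3.12 in Fin1-2 and 2.30% ± 3.05 in zf1fin3. It was uneven over the fin, from 0.0209% to 26.5% in pieces of Fin1-0. The scar 31M18D45M held 2.42% ± 2.11, 3.61% ± 2.79, 2.18% ± 1.48 and 2.25% ± 1.31 in the same order. In Fin1-0 the other named scar was 27M2D49M with 2.00% ± 2.05. In Fin1-1, Fin1-2 and zf1fin3 it was 27M11D49M, with 1.89% ± 0.827, 2.28% ± 1.23 and 2.26% ± 1.62. The uncut target held 73.5% ± 11.1, 73.6% ± 13.8, 76.4% ± 9.29 and 77.0% ± 9.32 in the 4 collections.

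Neighbours exceeded other pairs by 0.0706 in Fin1-0, 0.106 in Fin1-1, 0.0887 in Fin1-2 and 0.0796 in zf1fin3. The permutation p was 1e-04 in each collection, the smallest that the draws can give. Pieces of a fin are not replicates, the deposited tables name 1 fish, and zf1fin3 repeats Fin1-2, so the test speaks of this fish only. Mean profiles of Fin1-0 had a similarity of 0.909 with Fin1-1, 0.909 with Fin1-2 and 0.911 with zf1fin3, and Fin1-2 and zf1fin3 had 0.981. Without the uncut target these were 0.659, 0.704, 0.719 and 0.930. These are values of 1 profile per collection and were not tested.

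**Figure D4:**
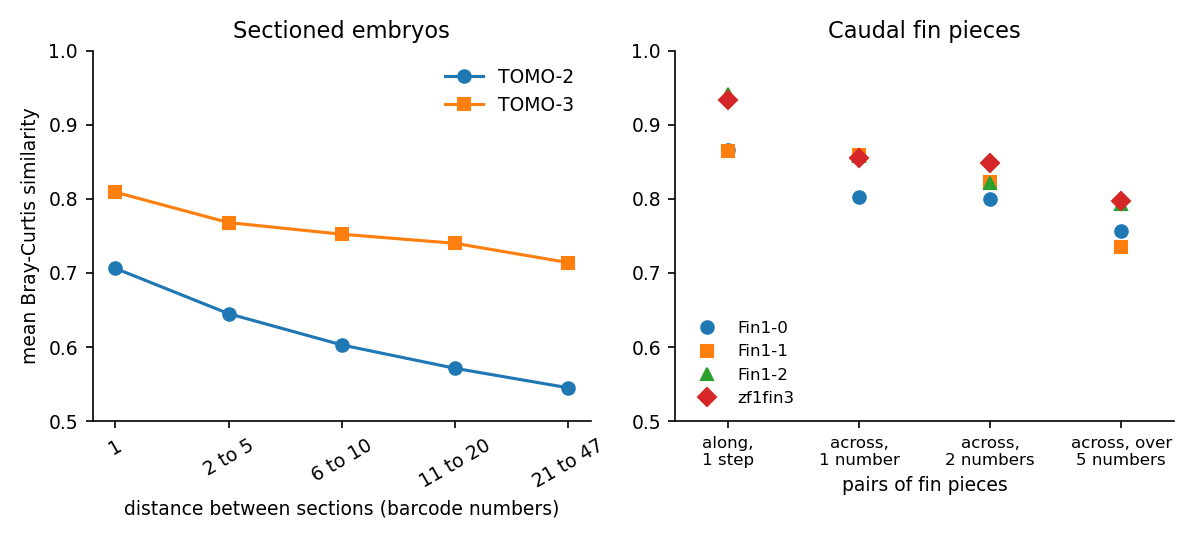
Mean Bray-Curtis similarity between sections against their distance in barcode numbers for the 2 sectioned embryos (lines), and between fin pieces by their relative position for the 4 fin collections (points). The vertical axes start at 0.5; similarity falls with distance, from 0.706 to 0.545 in TOMO-2 and from 0.865 to 0.756 in Fin1-0.

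F1 embryos show which scars reached the germline of an injected founder. Every F1 embryo of the protein clutches PF1-3 (n = 80) and PF1-4 (n = 86) carried 29M6D47M, with a median of 55.5% and 55.3% of reads. Beside it, 22M7D54M, 27M10D49M and 27M14D49M were carried most often. In PF1-3 embryos with at least 20000 reads, 14 of 35 carried 27M10D49M, 12 carried 22M7D54M, 8 carried 27M14D49M, 1 carried none of these and 0 carried more than 1. In PF1-4 the counts were 34, 15, 17, 1 and 0 of 67. Over all 80 embryos of PF1-3, 36 carried 27M10D49M, 43 carried 22M7D54M and 27 carried 27M14D49M. Over all 86 embryos of PF1-4 the carriers of these scars numbered 40, 18 and 24. Some PF1-3 embryos with fewer reads thus passed the 5% rule for more than 1 of the scars. In PF1-3 the median share of 22M7D54M was 14.0% over all carriers, against 26.6% in carriers with at least 20000 reads. Leaking reads stay open as the source of such additional scars.

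Clutches of founders injected with mRNA held many embryos without a scar. They were 64 of 85 embryos (75.3%) for RM7, 29 of 41 (70.7%) for RM1, 115 of 221 (52.0%) for RF8 and 48 of 77 (62.3%) for RM5. Named scars of RM7 were 27M2D49M in 14 embryos, 25M3D11M4D40M in 12 and 33M21D43M in 12, each with a median share of 14.3% to 15.4%. Those of RM1 were 26M3D50M in 11 embryos, 25M5D51M in 10 and 29M6D47M in 7. In RF8 they were 28M15D48M in 74 embryos (median 9.80% of reads), 58M18S in 25 and 25M12D51M in 8. In RM5 they were 31M18D45M in 21 embryos (median 61.7%), 26M3D50M in 15 (32.9%) and 25M1I50M in 7 (14.3%).

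An F1 embryo carried 2.40 ± 0.836 scars in PF1-3 (SD, n = 80) and 2.02 ± 0.265 in PF1-4 (n = 86). The value of PF1-3 includes embryos with fewer reads, in which leaking may have lifted scars past the 5% rule. The mRNA clutches had 0.624 ± 1.14 in RM7, 0.878 ± 1.49 in RM1, 0.507 ± 0.577 in RF8 and 0.662 ± 0.912 in RM5. Without library 2 of RM7 its embryos had 0.346, and with scars carried at 10% of reads those of RF8 had 0.208. Germline scars numbered 6 in PF1-3, 5 in PF1-4, 7 in RM7, 4 in RM1, 3 in RF8 and 4 in RM5. When 1 F1 embryo was enough they numbered 8 in RF8 and 6 in RM1 and RM5, with the other founders as before. They numbered 5.04, 4.87, 5.28, 4, 2.39 and 3.90 when each clutch was thinned to 41 embryos. Protein clutches exceeded mRNA clutches by 1.54 scars per embryo (2.21 against 0.668). Taken as 2 against 4 founders, the exact permutation p was 0.0667, the smallest this design allows, so the threshold was out of reach. PF1-3 and PF1-4 may be 1 founder, because they had 4 germline scars in common and their file names give PF1 for both. In that case the 2 clutches are not separate replicates. Counting PF1-3 and PF1-4 as 1 founder gave 1.54 (exact permutation p = 0.2), and without library 2 of PF1-3 its germline scars numbered 3 in place of 6. With a minimum of 5000 reads, an alternative chosen after seeing the data, PF1-3 and PF1-4 both had 4 germline scars.

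**Figure D5:**
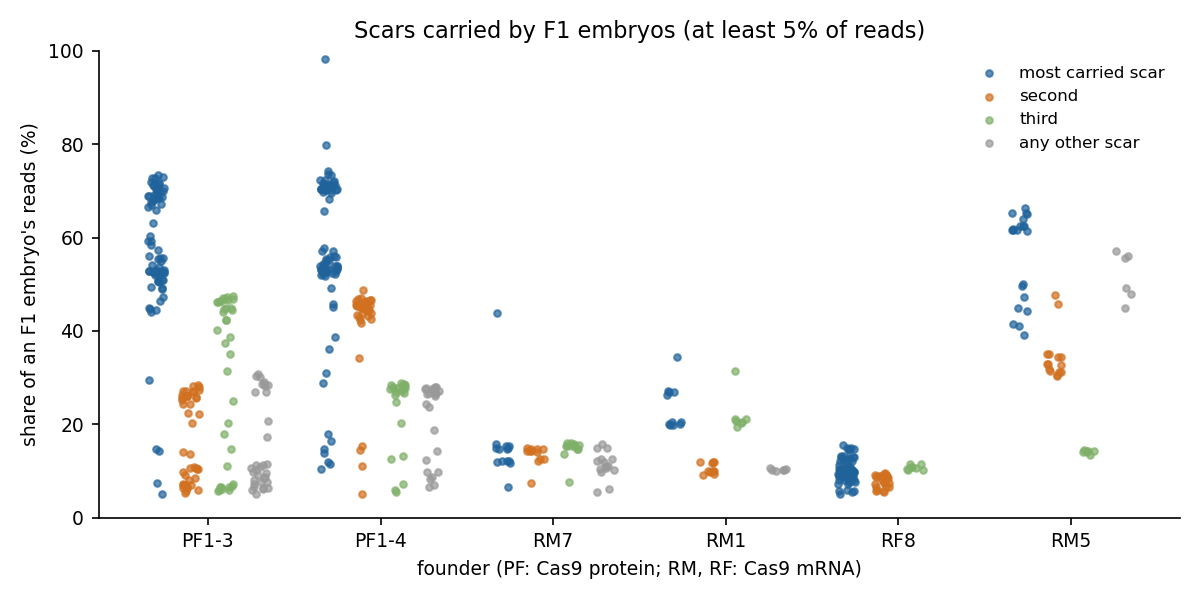
Share of an F1 embryo's reads (%) held by each scar it carried (at least 5% of reads) for the 6 founders, with a dot per embryo and scar and the 3 most carried scars of each founder in colour. Carried shares form bands, such as those of 31M18D45M in RM5 with a median of 61.7% and of 28M15D48M in RF8 with a median of 9.80%.

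Whole-genome coverage gave the number of reads over the transgene relative to the genome in 1 library without replicates. The 3 full bins of the transgene held a mean of 50.3 estimated counts (37.1 to 63.7), against a median of 8.23 (quartiles 5.10 and 11.7) over 1268725 bins of 24 chromosomes. This is a ratio of 6.11 (counting interval 5.18 to 7.17). With all listed bins, including those past the last bin with a read, the ratio was 9.32.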

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

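The comparisons of stage changes between experiments 3 and 4, the use of log10 reads as a covariate, leaving out consecutive barcode numbers in fins, private scars as the measure of leaking reads in embryos, and how often each scar shared by PF1-3 and PF1-4 arose in 24 h embryos were chosen after the data were seen; the other tests in this part were set before their results. Far values were looked for in 33 sets of embryos (group and measure), of which chance gives about 1 in 20, or 1.65, and 4 were found.

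Among the 6 embryos of the 24 h library of experiment 3, 1 embryo had 46.1% scarred reads (nearest other 19.2%) and 21 distinct scars (nearest 8), at 46425 reads. Among the 10 embryos of experiment 4 at 32 h, 1 had an effective number of scars of 76.3 (nearest 53.5). Among the 10 embryos of experiment 4 at 8 h, 1 had 61.2% scarred reads (nearest 35.7%).

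The change of the scarred share from 24 h to other stages was compared between experiments 3 and 4. Only the change to 72 h passed after adjustment. From 24 h to 72 h the scarred share changed by 22.6 points in experiment 3 and by -18.7 points in experiment 4, a difference of -41.3 (permutation p = 0.005, adjusted p = 0.025 over 5 stages). From 24 h to 32 h the changes were 16.8 and -12.7 points, a difference of -29.5 that did not pass after adjustment (permutation p = 0.0289, adjusted p = 0.0723). To 48 h and 6 d the differences were -21.5 (permutation p = 0.0793, adjusted p = 0.128) and -14.6 (permutation p = 0.266, adjusted p = 0.266). All share the 24 h groups, where experiment 4 lay 31.4 points above experiment 3. The 72 h means were 49.1% in experiment 3 and 39.2% in experiment 4, from 1 library each. A different change cannot be told apart from differences between libraries.

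Barcodes that the labels do not list had at least 1000 reads in 8 libraries, 53 barcodes in all, and their scarred shares lay above the highest control embryo (0.376%). In libraries with 1 such barcode the share was 13.1% (24 h library of experiment 3), 24.2% (32 h library of experiment 3), 45.3% (library 2 of mixed stages of experiment 3, 3029 reads), 22.6% (library of mixed stages of experiment 4, 1315 reads) and 99.7% (library 1 of PF1-3). The median was 30.1% over 9 barcodes of the 48 h DNA library, 34.5% over 36 barcodes of the 48 h RNA library and 17.2% over 3 barcodes of library E of zf1fin3.

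Embryos with fewer reads had a higher scarred share: the rank correlation of reads and scarred share was negative in 13 of 13 libraries with at least 6 embryos of a stage (mean -0.477, exact permutation p = 0.000244), though in the 48 h library of experiment 4 the lower-read embryos had a mean scarred share -10.7 points from that of the higher-read ones (mean over libraries 13.2). Reads leaking in proportion from all barcodes of a library draw embryos with few reads towards the share of the whole library. The lower-read embryos lay above that share in 13 of 13 libraries, by 14.1 points on average (SD 10.2, exact permutation p = 0.000244). Embryos with many reads set most of that share, so this largely restates the pattern. In the 48 h library of experiment 4 the lower-read embryos lay 8.36 points above it, though below the higher-read ones. The comparison therefore does not exclude leaking as a cause. By private scars, those of 1 well-read donor embryo that lay under 0.5% in all embryos of other libraries, leaking was also estimated. It may make up 12.6% of the reads of the lower-read embryos on average (SD 10.4). Most libraries gave only 1 private scar, and its share was scaled from the donor to all reads of the library. The same scar made independently in a lower-read embryo would count as leaked, so these values are not measured leak rates. The estimate ranged from 18.2% to 29.1% in libraries of experiment 3 and from 0.581% to 8.66% in those of experiment 4. Targets lost to deletions too long to amplify could lower the number of reads and stay open, since the rank correlation of scarred share with length changes over 20 bases averaged 0.157 (exact permutation p = 0.255) and the longest deletions leave no reads to count. With log10 reads as a covariate the step from 8 h to 24 h in experiment 4 was 24.3 points (permutation p = 0.00226). No biological explanation was tested.

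The F1 embryos of PF1-3 and PF1-4 carried the same scars, with 4 germline scars in common. Their shares matched as well in embryos with at least 20000 reads. Medians of 27M10D49M, 22M7D54M and 27M14D49M were 46.3%, 26.6% and 28.7% in PF1-3, and 45.2%, 26.7% and 27.8% in PF1-4. The scars 22M7D54M and 27M10D49M were each found in 1 of 30 embryos with protein or mRNA at 24 h (3.33%, interval 0.0844% to 17.2%). This argues against scars frequent enough to arise in 2 founders independently. It does not exclude them, since the protein embryos were only 12 and the mRNA embryos pooled with them differed in their scars. This explanation stays open for 29M6D47M, found in 100%, and for 27M14D49M, found in 13.3% (interval 3.76% to 30.7%). Of the 4 scars, 3 were found in at most 1 of the 12 with protein. Reads leaking between the libraries of the clutches are excluded for carriers with at least 20000 reads, where the lowest median share of a shared scar was 26.6%. This minimum was not part of the test as set before. Over all 43 carriers of PF1-3 the median share of 22M7D54M was 14.0%, so leaking in embryos with fewer reads stays open. A common mother, related founders or 1 founder under 2 labels (the file names give PF1 for both) may account for the shared scars; this stays open and was not tested. Counted as 1 founder, the clutches exceeded the mRNA clutches by 1.54 scars per embryo (exact permutation p = 0.2).

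Neighbouring fin pieces were more similar than other pairs in the 4 collections. Reads leaking between consecutive barcode numbers are excluded as the whole cause: in Fin1-1, 67 pairs of consecutive barcodes that are not neighbours exceeded other pairs by 0.0143 (permutation p = 0.269), against 0.0975 for neighbours within libraries, and with consecutive numbers left out neighbours exceeded other pairs by 0.0694 in Fin1-0, 0.110 in Fin1-1, 0.0543 in Fin1-2 (0.0887 with them) and 0.0479 in zf1fin3 (0.0796 with them; permutation p = 1e-04 in each). Neighbours sequenced in the same library are excluded as the whole cause too, since with pairs of 1 library alone neighbours stayed more similar in 4 of 4 collections of 1 fish, of which zf1fin3 repeats Fin1-2, by 0.0637 in Fin1-0, 0.0975 in Fin1-1, 0.0690 in Fin1-2 and 0.0379 in zf1fin3 against 0.0796 with all pairs of zf1fin3 (permutation p = 1e-04 in each, the smallest possible). Clones that occupy connected parts of the fin remain a hypothesis, since it was found and examined on the same data. No biological explanation was tested, because the design holds no group that differs in its clones.

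For the named scars, other splits of the same embryos show how many scars differ when embryos are grouped at random. For protein against mRNA embryos 4 scars differed, the highest of the other splits gave 2, and 1 of 100 splits, the real one, reached 4. Random grouping over this list thus did not give as many. The list was chosen by high share in these mRNA embryos, which favours scars lower with protein, and the protein embryos were 1 library. The splits cannot exclude either as the cause. For 6 d against 8 h the real number was 0 and the highest other 2, and for dCas9-labelled against mRNA embryos it was 0 and the highest other 1. With a real number of 0, 100 of 100 splits reach it whatever the data, so these counts say nothing about chance.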

How the results depend on the processing

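Log10 reads as a covariate, right-clipped reads as deletions, all scarred reads as the denominator of lengths, all listed bins, PF1-3 and PF1-4 as 1 founder, leaving out each founder, leaving out consecutive barcode numbers in fins, and the minimum of 5000 reads for adjacent stages, named scars and F1 clutches were chosen after seeing the data; the other alternatives were set before. Over 44 results and 241 alternatives, 218 kept the direction and the side of the threshold or moved by less than the spread (for counts, by at most 1.5 times), 9 were weaker, 2 stronger, 9 moved and 3 turned direction. The step from 8 h to 24 h in experiment 4 stayed past the threshold under every alternative run. So did both comparisons with Cas9 alone and the similarity of neighbouring sections and fin pieces. The 4 scars lower with protein had only 1 alternative run, a minimum of 5000 reads, and stayed past the threshold with it. All protein embryos had at least 37093 reads, so this minimum left out none of them. The comparison of 6 d with 24 h stayed short of the threshold in both experiments.

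The dCas9-labelled difference (-18.5 points, unadjusted permutation p = 0.0256) ended its call with a minimum of 5000 reads (-15.5, p = 0.0581), medians (-22.3, p = 0.147), experiment 3 alone (-1.04, exact permutation p = 0.898), log10 reads as a covariate (-5.03, p = 0.544) and without either of its libraries (-18.6, exact permutation p = 0.0956, and -18.3, exact permutation p = 0.103). With a minimum of 5000 reads the deletion share at 24 h minus 8 h turned to -0.476, and with right-clipped reads as deletions to -0.267, both far from the threshold. Scars under 1% counted as uncut turned the effective number at 24 h minus 8 h to 3.77 (permutation p = 0.00229), and brought the RNA minus DNA background to 0, since no background change reaches 1%. That background difference was 0.148 (permutation p = 0.0692) from 100 reads and 0.0413 (permutation p = 0.340) with 1000 reads per barcode. Scars counted from 0.1% of reads gave a protein minus mRNA difference of -16.7 distinct scars (permutation p = 0.0176). Leaving out the farthest embryo of each group gave -4.74 for length changes divisible by 3 (permutation p = 0.0344). Similarity of mean fin profiles with scars from 1% was 0.923 for Fin1-0 with Fin1-1 and 0.946 for Fin1-0 with Fin1-2, and leaving out 1 library gave 0.864 to 0.910 for the latter. Germline scars of PF1-3 numbered 3 to 6 without either of its libraries, and those of RF8 numbered 8 when 1 F1 embryo was enough. In PF1-4 the scars per F1 embryo were 2.33 with scars carried at 2% and 2.33 from 100 reads. The transgene ratio with all listed bins was 9.32, where empty bins lower the median by construction. For the others the cause was not tested.

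No paired analysis was possible because replicate numbers in the labels number libraries, which hold different fish or, for fins, different pieces of 1 fish, and 1 library often holds a whole group, so a replicate block was not run. Leaving out each sectioned embryo was not run either, as each was already tested alone. Depth limits rare scars most: at 1000 reads a scar below 0.3% of the target can go unseen.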

Other observations

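The tests of ray numbers, of barcode pairs at 48 h, of steps in F1 shares and of telomere repeats were chosen after the patterns were seen; that of microhomology was set before its result.

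Regenerated fin pieces resembled original pieces at the same ray number. With the uncut target left out, pieces of Fin1-0 and Fin1-1 at the same ray or interray number had a similarity of 0.477, against 0.337 at other numbers, a difference of 0.140. It was 0.147 for Fin1-0 with Fin1-2 and 0.155 for Fin1-0 with zf1fin3 (permutation p = 1e-04 in each, the smallest possible). The hypothesis that ray positions keep their clones through regeneration would give such a difference, but this hypothesis was formed on the same data. Ray numbers were permuted freely although pieces at nearby numbers resembled each other, so p may be too small. Other numbers pooled nearby with distant ones, so the same number was not told apart from the same region of the fin. As zf1fin3 repeats Fin1-2, their comparisons are not separate. Similarity along a ray or interray was taken with the uncut target included. For pieces 2 steps apart it was 0.806 in Fin1-0, 0.806 in Fin1-1, 0.916 in Fin1-2 and 0.910 in zf1fin3. Across the fin, at numbers 2 apart, it was 0.799, 0.823, 0.822 and 0.848 in the same order. In Fin1-1 the value across was thus the higher one.

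Scars found in many embryos were often deletions between short repeats. Single deletions of at most 20 bases with at least 2 bases of microhomology at their ends were found in 10.3 ± 7.84 of the 24 h embryos (SD, n = 9 deletions), others in 3.43 ± 4.44 (n = 23). The difference of 6.90 embryos passed an exact permutation test over deletions (p = 0.00393), and 5 of the 8 single deletions of at most 20 bases found in at least 9 embryos had such repeats. Repair through microhomology at the deletion ends may favour them, though 27M2D49M, 27M9D49M and 27M6D49M were widespread with 1 base.

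Some reads clipped at the cut held telomere repeats. Of 1468 clipped sequences 76 held 10 bases of the repeat, against 4 in the highest of 100 shuffles of their bases. Reads with the repeat made up 0.0984% of reads on average in 141 injected embryos and pools and 0.000772% in 45 embryos without sgRNA. The most frequent, 27S49M_2 with GTGCTAACCCTAACCCTAACCCTAACC in place of the aligned bases, had 288662 reads and held at least 0.5% of reads in 15 of 68 pieces of Fin1-0, 16 of 82 of Fin1-1, 8 of 43 of Fin1-2 and 13 of 80 of zf1fin3. Another, 27S49M_5, was carried by 2 of 85 F1 embryos of RM7. A candidate explanation is that DNA with telomere repeats was joined at the cut, which these 76 sequences would allow; joining during PCR in scarred samples was not tested.

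Barcodes outside the labels in the 48 h libraries resembled each other across molecules. For 8 of 9 such DNA barcodes, the most similar of 37 RNA barcodes was the one numbered 24 higher, and the listed barcodes of these libraries have the same offset. The similarity of the 9 best matches was 0.917 to 0.953. The hypothesis that RNA barcode numbers lie 24 above the DNA number of the same embryo may account for this, but no label gives it.

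Shares of F1 scars formed steps. In F1 embryos from 5000 reads on, the lowest typical share of a germline scar had a median of 12.1% over 6 founders (SD 9.13). It ran from 5.92% in RM7 to 27.0% in PF1-4, which may be the same founder as PF1-3. The value of RM7 came from 27S49M_5 in 2 embryos, near the 5% rule that bounds this share from below. Named scars of RM7 had medians of 14.3% to 15.4%. With more carriers, the lowest share was 10.0% in RM1 (10 carriers) and 8.28% in RF8 (24 carriers). If a step is 1 copy of the transgene, the coverage of a homozygous fish puts it at 16.4% (counting interval 13.9% to 19.3%; 12.9% to 22.2% from the highest and the lowest full bin). The hypothesis that one scar step is one copy of the transgene could not be decided, since the founders differ by more than the gap between these values and a scar may be present in several copies.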
